A study of Homo sapiens with 2 samples.

How the data were processed

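Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line, on 2 Agilent 1-colour arrays. Per the labels, 1 array held Cy3-labelled cRNA from cells transfected with a control siRNA and 1 array cRNA from cells transfected with siRNA against ZNF746, both at 48 h. The groups were taken from the transfection field of the labels, while the transfection protocol is the same text for both samples. The labels describe 1 sample per group and do not say how many cultures it holds. Per the file headers, both arrays were on 1 slide and had 1 scan time, so slide and scan did not differ between the groups.

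The deposited array files hold spot intensity values on a linear scale. Per the file headers, Feature Extraction 11.5.1.1 read the spots, subtracted the background, corrected a spatial trend within each array and gave dim spots a small positive surrogate value. The deposited value table holds log2 values whose making is not given in the sources used here. Set against the scanner values, its columns equalled the log2 of the processed intensity within a tolerance of 0.001 for all 33128 probes printed once. Its column medians were 5.956 for control siRNA and 6.018 for ZNF746 siRNA, so it was neither scaled between arrays nor centred on genes.

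Each array had 44495 spots, of which 43118 were not controls. They belonged to 34127 probes, 33128 printed once and 999 printed 10 times. Spots marked as outliers in the files, 307 on the control siRNA array and 277 on the ZNF746 siRNA array, were left out, and no spot was saturated. A probe counted as well above background where the files mark at least a share of 0.5 of its spots so. This held for 23574 probes (69.1%) on the control siRNA array and 23954 probes (70.2%) on the ZNF746 siRNA array. Of the 320 spike-in control spots, 38 and 39 were well above background, and they were not used for scaling.

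The log2 processed intensity was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. That percentile was an intensity of 607 for control siRNA and 604 for ZNF746 siRNA. Probes were named through their RefSeq accessions in a gene table of assembly GRCh38.p14, which is another build than the one the file headers name, so no coordinates are given. A symbol was found for 25771 probes, covering 19740 genes, and 8356 probes stayed unnamed. A gene's value was the mean over its probes well above background on both arrays, and 14638 genes were measured in this way. All differences are ZNF746 siRNA minus control siRNA on the log2 scale. Near-identical gene copies were not resolved, and values of histone and ribosomal protein genes are uncertain where a probe can bind several copies.

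With 1 array per group there are no residual degrees of freedom, so no test, standard error or p-value is given for any gene. Genes were counted by size, at least 2-fold either way. The number of arrays limits the precision, and the only errors that could be measured were technical. The median SD of the difference was 0.048 over spots of 1 probe (771 probes with at least 5 usable spots on both arrays) and 0.096 between different probes of 1 gene (3573 genes). Neither holds the variation from culture to culture.

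For each of 30 gene lists the median difference of the measured members was set against 10000 random lists of the same size. Each member was replaced by a gene drawn from the 200 nearest in mean signal. A list was said to stand apart when its median lay under the 2.5 or over the 97.5 percentile of the random medians. The percentile describes these 2 arrays only. Random lists ignore that genes of a pathway vary together, so more lists stand apart than the nominal 5%. In simulated arrays of 14638 genes, 7% of 200 lists of 25 genes with no shift set stood apart, and so did 100% of 20 lists shifted by -0.3. Lists with no shift set could hold some of the shifted genes. The simulation shuffled differences among probes of like signal, so its genes did not vary together. The 7% therefore does not give the rate for pathway lists. Of 50 genes given a log2 change of 1.5, 96% passed 2-fold with a median of 1.56. The shares were 90% at -1.5, 30% at 0.75 and 12% at -0.75.

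The gene lists, the comparisons, most alternatives and the rule for named genes were fixed before the data were examined. The rule took ZNF746, and the 12 highest and 12 lowest genes of above-median signal whose probes had 1 sign. It also took up to 4 members of each list at 2-fold or otherwise the 2 largest, the reference genes as a range, and up to 5 genes each way among those above background on 1 array only. Some genes that meet this rule are not reported here. For genes above background on 1 array only the fold is a lower bound. It sets the brighter array against the higher of the dim probe's own value and the lowest signal well above background on its array.

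The alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), quantile normalization, median scaling, the 75th percentile over probes well above background on both arrays, and loess of the difference on mean signal (span 0.3). Others used probes above background on at least 1 array, no filter, the brightest probe of each gene, the authors' value table, a 1.5-fold threshold, unmatched random lists, list means and a 5th percentile floor. Normexp had been meant for mean spot signals, and median spot signals were used because the array files analysed here have no mean signal column. A correction by blocks of 28 rows by 17 columns, a restriction to genes with 2 or more measured probes, and 9 further gene lists were chosen after seeing the data. The calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.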

Results

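RNA from HCT116 cells, a human colorectal carcinoma line, was compared between a control siRNA and an siRNA against ZNF746, 48 h after transfection. ZNF746 encodes PARIS, a zinc finger repressor that is known to repress PPARGC1A. The comparison asked which transcripts differed when ZNF746 was targeted. Each group had 1 array, so no difference has a replicate check, and every value is the log2 difference of ZNF746 siRNA minus control siRNA unless stated otherwise. The median probe intensity was 62.1 in control siRNA and 64.8 in ZNF746 siRNA, and 69.1% and 70.2% of probes were well above background. On the 2 arrays 14638 genes were measured, and their signals correlated across genes with r = 0.993, where genes are not independent replicates.

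The targeted transcript itself was lower in the ZNF746 siRNA array with both of its probes. The brighter ZNF746 probe had an intensity of 3386 in control siRNA and 1977 in ZNF746 siRNA, 41.3% lower after scaling (-0.77). The dimmer ZNF746 probe had 113 and 77.1, 31.7% lower (-0.55). Their mean of -0.66 ranked 312 from the lowest among the 14638 genes, so many other transcripts were lower by more than the target. Over the alternatives tried the ZNF746 value lay between -0.77 and -0.57.

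At least 2-fold differences were found for 173 genes, 1.18% of those measured, with 117 higher and 56 lower in ZNF746 siRNA. Most of the higher genes were dim. Among the dimmest of 4 equal groups by mean signal, 79 genes were at least 2-fold higher and 25 lower, while among the brightest 1 was higher and 13 lower. The counts rest on 1 probe for 157 of the 173 genes. For the 16 with several measured probes, 0 had probes of both signs, which a mean past 2-fold makes likely in advance. Among all 3573 genes with several measured probes, 1070 had probes of both signs. The differences of 2 probes of 1 gene correlated across genes with r = 0.58. The share of higher genes was 67.6%, but 53.4% (86 higher and 75 lower) with median scaling and 50% (17 and 17) with normexp background correction.

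**Figure D1:**
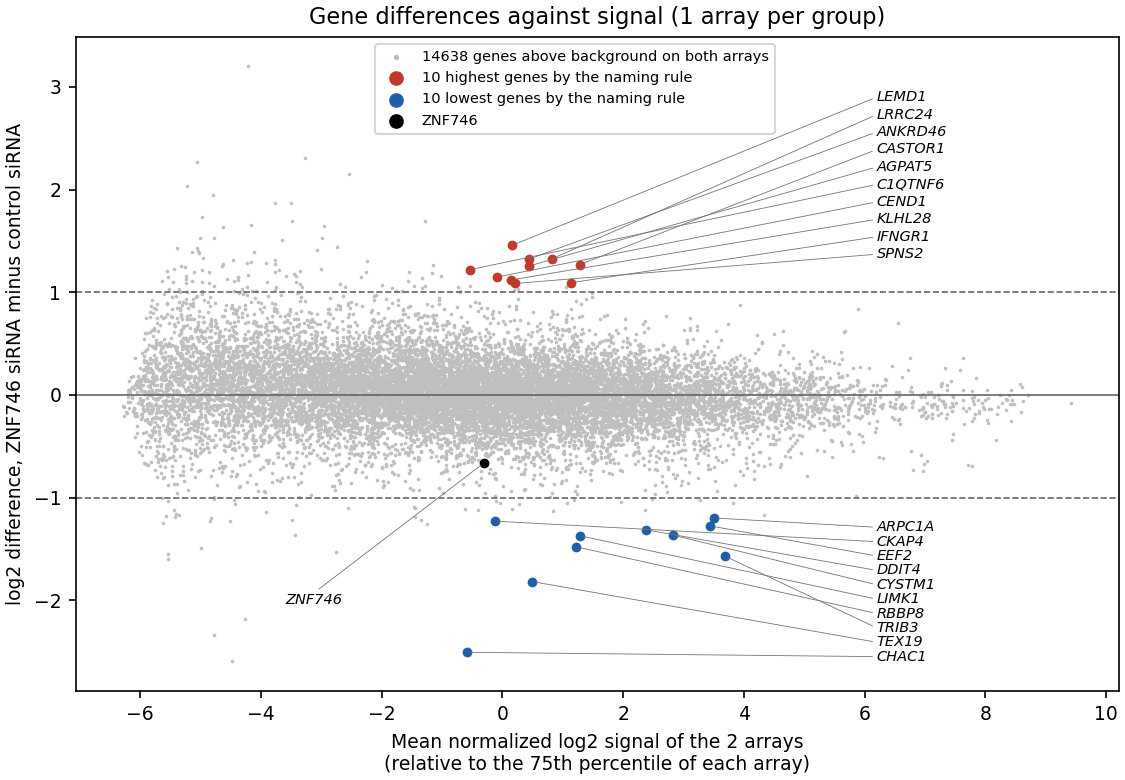
Log2 difference of each measured gene (ZNF746 siRNA minus control siRNA, y axis) against its mean normalized log2 signal on the 2 arrays (x axis), with 1 point per gene and dashed lines at 2-fold. The 10 highest and 10 lowest genes of above-median signal, by the rule for named genes, are coloured, from LEMD1 at 1.46 to CHAC1 at -2.51, and ZNF746 lies at -0.66.

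Among well-expressed genes, the lowest in ZNF746 siRNA was CHAC1, an enzyme that degrades glutathione, at -2.51 (5.69-fold lower, probes -2.71 and -2.31). TEX19, a germline gene, was at -1.82, the pseudokinase TRIB3 at -1.57 and RBBP8, which acts in DNA end resection, at -1.48. LIMK1, a kinase of the actin regulator cofilin, and CYSTM1 were both at -1.37. DDIT4, an inhibitor of mTORC1, was at -1.32 and the translation elongation factor EEF2 at -1.28. CKAP4 (-1.23), the Arp2/3 subunit ARPC1A (-1.20), the proteasome subunit PSMA3 (-1.17) and the hexokinase HK2 (-1.13) completed the 12 lowest. HK2 was at -0.61 when dim probes were kept, and the other 11 stayed under -1 in all alternatives tried.

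The highest well-expressed gene was LEMD1 at 1.46 (2.74-fold), followed by LRRC24 and ANKRD46, both at 1.32. CASTOR1, an arginine sensor of the mTORC1 pathway, was at 1.27 with probes at 1.24 and 1.30. AGPAT5, an acyltransferase of phospholipid synthesis, was at 1.26, C1QTNF6 at 1.22, CEND1 at 1.15 and KLHL28 at 1.12. IFNGR1, a chain of the interferon gamma receptor, and SPNS2, a sphingosine-1-phosphate transporter, were both at 1.09. The aldo-keto reductase AKR1C3 was at 1.06.

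Of 30 gene lists 15 stood apart from random lists of like signal, 7 lower and 8 higher, against 1.5 at a nominal 5%, which is a low estimate for genes that vary together. The joint list of integrated stress and unfolded protein response genes had a lower median in ZNF746 siRNA. Of 26 measured members 24 were lower and 2 higher, with a median of -0.40, lower than all 10000 random lists (percentile 0). The 4 members past 2-fold were CHAC1, TRIB3, DDIT4 and PSAT1, an enzyme of serine synthesis (-1.05). Members singled out after their values were seen were the transcription factors ATF4 (-0.68) and DDIT3 (-0.87), and ASNS (-0.60), the asparagine synthetase. Among chaperone genes, picked out in the same way, HSPA5 (-0.091) and HSP90B1 (-0.13) differed less and DNAJB9 was higher at 0.73. The list kept its side of the threshold in all 13 alternatives, with a value between -0.54 and -0.38.

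**Figure D2:**
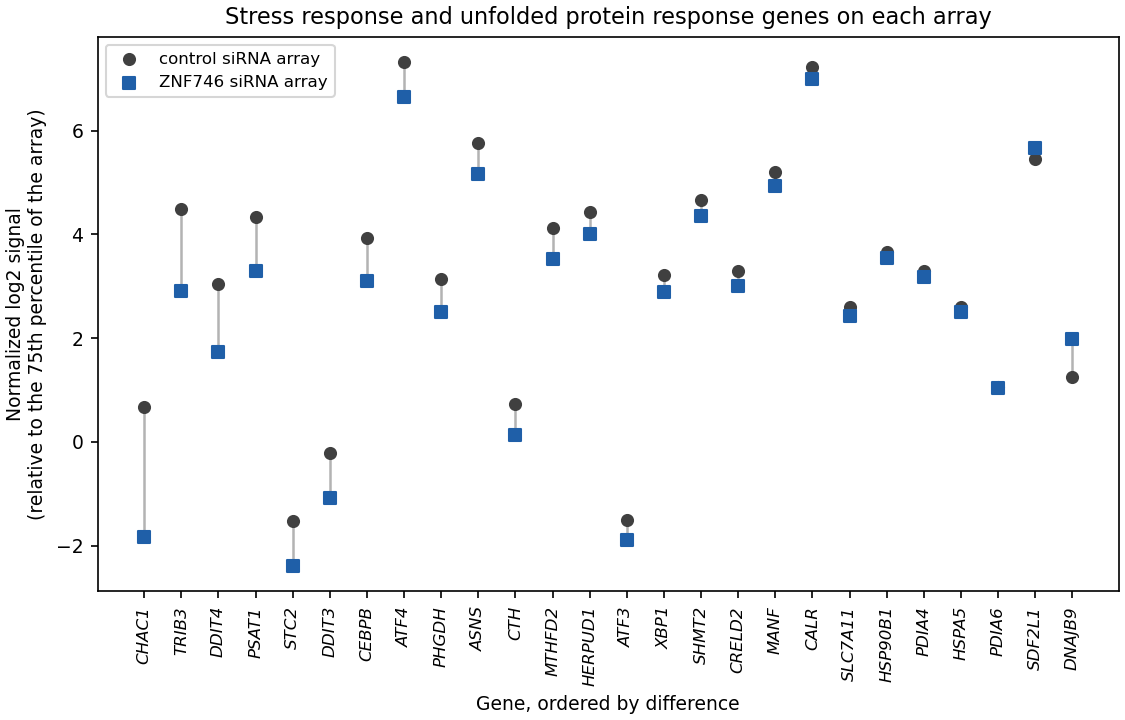
Normalized log2 signal (y axis, relative to the 75th percentile of each array) of the 26 measured stress and unfolded protein response genes (x axis, ordered by difference), with 1 circle for the control siRNA array, 1 square for the ZNF746 siRNA array and a line joining them. The square lies below the circle for 24 genes, with the widest gap for CHAC1, and above it for SDF2L1 and DNAJB9.

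Cell cycle genes were lower in ZNF746 siRNA in both phases examined. All 33 measured G2/M genes were lower, with a median of -0.34, and among them MKI67, the proliferation marker Ki-67, was at -0.68 (3 probes from -1.02 to -0.46) and NUSAP1, a spindle protein, at -0.64. Of 33 G1/S genes 31 were lower, with a median of -0.29. CDC25A, a phosphatase that activates cyclin-dependent kinases, was at -0.93 and UHRF1, which maintains DNA methylation, at -0.77. Both lists lay below all 10000 random lists (percentile 0).

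The lists of growth and chromosome maintenance went the same way. All 29 measured MYC and nucleolar genes were lower (median -0.35), including MYC itself at -0.94 and NPM1, encoding nucleophosmin, at -0.99 with 3 probes between -1.04 and -0.95. DNA repair genes had a median of -0.35 with 23 of 25 lower, RAD54L at -0.59 and FANCI at -0.56. Replication-dependent histones had a median of -0.48 with 14 of 16 lower, H2AC6 at -0.74 and H3C4 at -0.70. Each of these 3 medians was below all random lists (percentile 0). For the MYC list this ended with the 4 members that had 2 or more measured probes, where the median was -0.29 at percentile 5.22. Proteasome genes were lower in 25 of 27 cases (median -0.19, percentile 0.39), led by PSMA3, but the 6 with 2 or more probes, at a median of -0.18, lay at percentile 17.7.

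**Figure D3:**
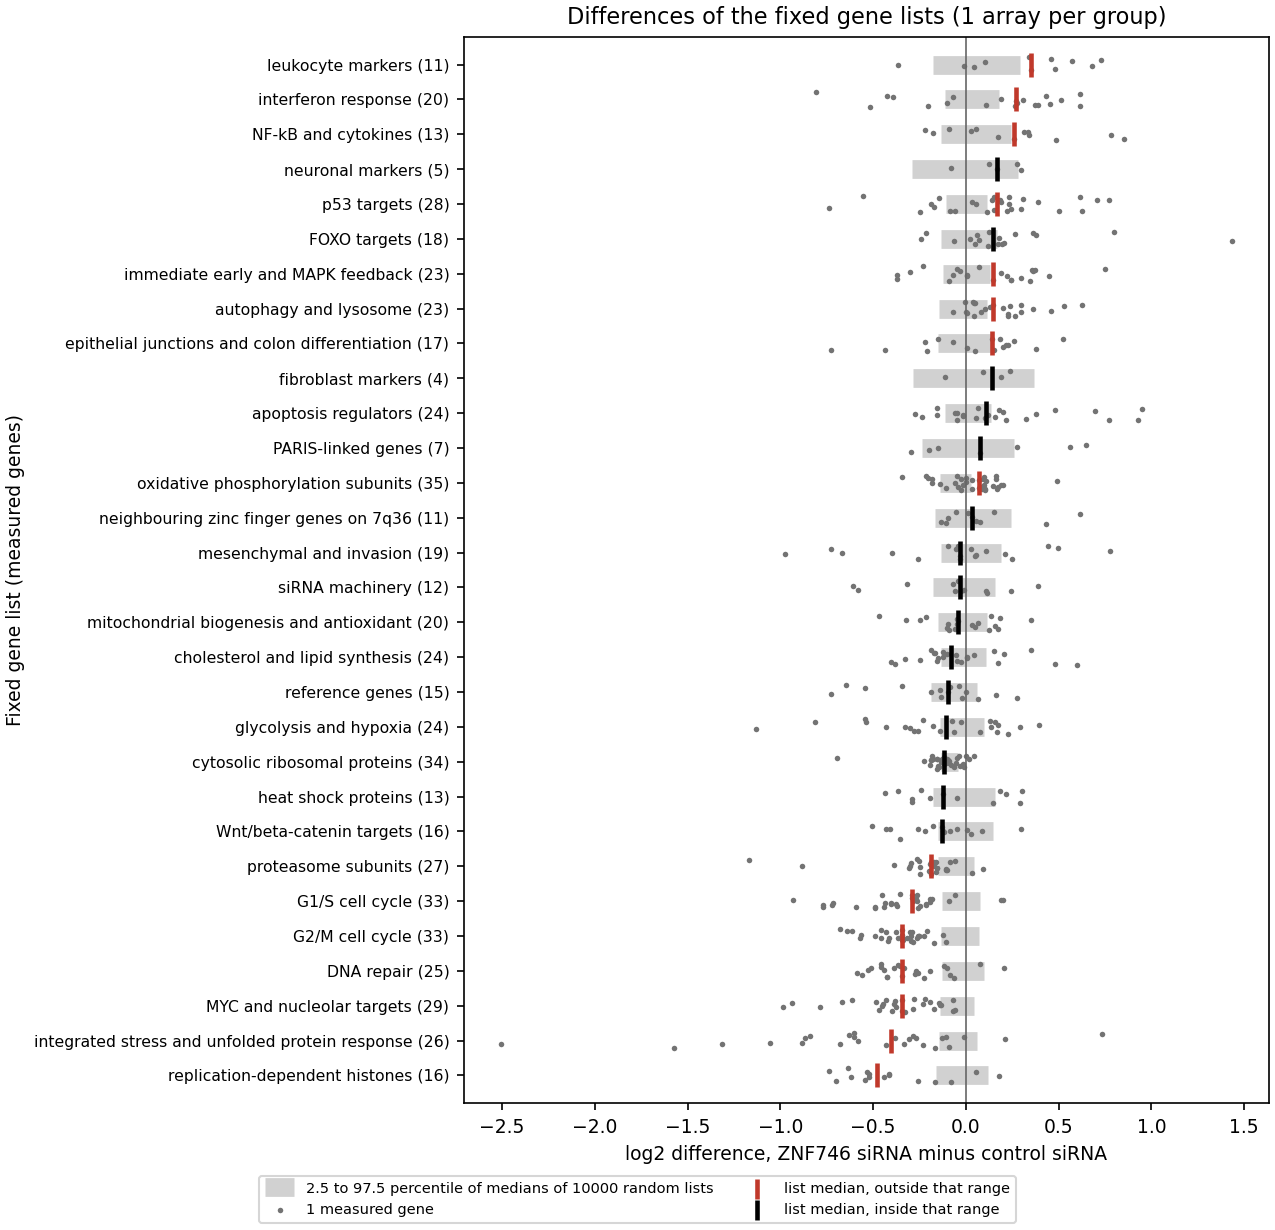
Log2 difference (x axis, ZNF746 siRNA minus control siRNA) of the measured genes of the 30 fixed lists (y axis, number of measured genes in brackets), with 1 dot per gene, a bar at the list median and a grey band for the central range of medians of 10000 random lists. Medians outside the band are red, 7 lower and 8 higher, from -0.48 for histones to 0.35 for leukocyte markers.

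Lists of p53 targets, of autophagy and lysosome genes, and of inflammatory genes had higher medians in ZNF746 siRNA. Of 28 measured p53 targets 20 were higher (median 0.17, percentile 99.8). TIGAR, a regulator of glycolysis, was at 0.77, while GDF15, a stress-induced cytokine, was at -0.74. Singled out after their values were seen, CDKN1A was at 0.24 and MDM2 at 0.04. With the 10 members that had 2 or more probes the p53 percentile was 87.8. Autophagy and lysosome genes were higher in 20 of 23 cases (median 0.14, percentile 99.1), with the lysosomal channel MCOLN1 at 0.63 and LAMP2 at 0.53, although the 3 LAMP2 probes ranged from -0.25 to 1.28. That call ended with normexp background correction (0.097, percentile 96.9) and in 2 other alternatives.

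NF-kB and cytokine genes had a median of 0.26 with 10 of 13 higher (percentile 98.4). The chemokines CXCL8 and CXCL1 were at 0.85 and 0.78, and over the alternatives between 0.32 and 0.86 and between 0.49 and 0.99. The NF-kB call ended in 4 alternatives, with a median of 0.056 at percentile 53.5 for the 5 members with several probes. Interferon response genes had a median of 0.27 with 13 of 20 higher (percentile 99.85). They went both ways, with IFIT2, an antiviral effector, at 0.62 and OAS3, a sensor enzyme for double-stranded RNA, at -0.81 (-0.87 to -0.28 over the alternatives). The mean of the interferon genes, 0.11, lay at percentile 83.85.

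Immediate early and MAPK feedback genes were higher in 15 of 23 cases (median 0.15, percentile 98.9), with PHLDA1 at 0.75 and the AP-1 subunit JUN at 0.45. Their call ended in 5 of 13 alternatives, and for the 2 members with several probes the median was -0.18. Epithelial genes had a median of 0.14 with 11 of 17 higher (percentile 97.8). CA2, a carbonic anhydrase, was at 0.52 and the intestinal antigen GPA33 at -0.73 (-0.82 to -0.16 over the alternatives). Only 4 of 13 alternatives kept the epithelial call, and the list median was -0.072 with no filter on dim probes.

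Genes tied to PARIS in earlier work did not stand apart as a list. Of 11 members 7 were measured, with a median of 0.078 (percentile 73.6). PINK1, a mitochondrial kinase, was at 0.65. PPARGC1A, PCK1, G6PC1 and IGFBP1 were not well above background on either array, so no fold is given for them. Mitochondrial biogenesis and antioxidant genes had a median of -0.044 (percentile 34.8), with GABPB1 at -0.47 and MFN2, a mitochondrial fusion protein, at 0.35, and the sign of the median turned with normexp, quantile and loess scaling. Oxidative phosphorylation genes had a median of 0.069 with 21 of 35 higher, NDUFS3 at -0.35 and UQCRB at 0.49 (probes 0.05 and 0.93). This was high against genes of like signal (percentile 99.8) but not against all measured genes (percentile 83.3), and the 7 members with several probes had a median of -0.00016.

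The zinc finger genes neighbouring ZNF746 had a median of 0.032 (percentile 50.9, 11 measured), with ZNF862 at 0.61 and ZNF425 at 0.43, and the sign of this median turned with quantile, median and loess scaling. Components of the siRNA machinery had a median of -0.034 (percentile 36.15), with TNRC6C at -0.61 and XPO5 at -0.58. Over the alternatives TNRC6C lay between -0.67 and -0.39 and XPO5 between -0.65 and -0.21. The 15 reference genes ranged from -0.72 for TFRC, the transferrin receptor, to 0.27 for YWHAZ, with a median of -0.099 (percentile 33.8).

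The other metabolic and signalling lists stayed inside the range of random lists. Wnt/beta-catenin targets had a median of -0.13 (percentile 5.66, 12 of 16 lower), with RNF43 at -0.50 and AXIN2 at -0.43. Glycolysis and hypoxia genes had -0.11 (percentile 8.25), with HK2 the member past 2-fold. FOXO targets had 0.15 (percentile 95.7, 15 of 18 higher), and FBXO32, a muscle-wasting ubiquitin ligase, was 2.71-fold higher at 1.44, but at 0.81 with normexp correction. Apoptosis regulators had 0.11 (percentile 94.1), with BMF at 0.95 and BCL2A1 at 0.93, whose lowest values over the alternatives were 0.39 and 0.41. Using list means in place of medians put these 4 lists outside the range, at -0.15, -0.15, 0.22 and 0.19.

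Cholesterol and lipid synthesis genes had a median of -0.079 (percentile 14.4; SC5D 0.60, HMGCS1 0.48) and heat shock proteins -0.12 (percentile 10.3; HSPH1 -0.43, HSPB1 -0.36). Cytosolic ribosomal proteins had -0.12 with 31 of 34 lower (percentile 15.5), and RPL37 was at -0.22. Their matched random lists, which can hold ribosomal genes themselves, had a median of -0.096, so this percentile says little. Against unmatched random lists the percentile was 0.87. Mesenchymal genes had -0.030 (percentile 25.3), with CCN2, a secreted target of YAP, at -0.97.

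Some markers of other cell types were measured. Of 15 leukocyte markers 11 were measured, 9 of them higher, with a median of 0.35 (percentile 99.3) and HLA-DRA at 0.73. With normexp correction that median was 0.075 (percentile 85.9). Fibroblast markers had 4 of 14 measured (median 0.14, percentile 71.5; DPT 0.24, COL1A1 0.19) and neuronal markers 5 of 12 (median 0.17, percentile 86.7; MAP2 0.30, TUBB3 0.28).

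Some genes were well above background on 1 array only and have bounds in place of folds. RNASE11 was at least 10.0-fold higher in ZNF746 siRNA, LRP2BP at least 7.93-fold, RYR3, a calcium release channel, at least 7.01-fold, SYT11 at least 4.21-fold and DLEC1 at least 3.77-fold. In the other direction NXF2 was at least 5.35-fold lower, the cytokine IL5 at least 4.61-fold, CR1L at least 4.27-fold, CCN4 at least 4.13-fold and SIRPD at least 3.90-fold. A bound of at least 2-fold was reached by 53 genes higher and 37 lower in ZNF746 siRNA. With the 5th percentile of the signals well above background as the floor these were 7 and 5 genes, and the bounds were lower, such as 5.84-fold for RNASE11, 4.61-fold for LRP2BP, 4.08-fold for RYR3 and 2.81-fold for NXF2.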

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

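Probes without a gene symbol took no part in the gene comparisons, and some of them differed strongly. Of 4222 unnamed probes well above background on both arrays, 28 were at least 2-fold higher in ZNF746 siRNA and 20 were at least 2-fold lower. The lowest was at -2.11 and the highest at 1.88 on the log2 scale. No replicate check exists for them, and no explanation was tested.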

How the results depend on the processing

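The block correction and the restriction to genes with 2 or more measured probes were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and a fit with the slide as a block was not run for that reason. Signal over background limits the dim genes most. Scaling moved the median of all genes by less than 0.1, and no named gene turned its sign. Among single named genes 728 values lay within the spread between probes and 52 moved beyond it, 29 of them with normexp. Stress, G1/S, G2/M, DNA repair and histone lists stood apart in all 13 alternatives, where the highest percentiles were 1.82, 0.33, 1, 2.16 and 0.05. Over all lists 347 values kept their call, 10 newly stood apart, 25 no longer did and 4 values of lists that had stood apart turned.

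The counts of at least 2-fold higher and lower genes were 17 and 17 with normexp, 278 and 159 with probes above background on at least 1 array, and 519 and 403 with no filter, against 117 and 56. Of the 117 and 56, 106 and 54 were shared with the unfiltered counts, and all 17 and 17 of normexp were among them. At 1.5-fold there were 648 and 471. Genes with a bound of at least 2-fold were 7 and 5 with the 5th percentile floor. More genes passed where dim probes or smaller folds were let in.

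With normexp the medians no longer stood apart for NF-kB (0.14), autophagy (0.097), epithelial (0.095), immediate early (0.087) and leukocyte lists (0.075). With no filter NF-kB genes were at 0.087, epithelial genes turned to -0.072 and heat shock proteins newly stood apart (-0.195). With probes above background on at least 1 array, epithelial genes lost their call (0.051) and heat shock proteins gained it (-0.195). Epithelial genes also lost it with loess (0.15), the brightest probe (0.14) and the block correction (0.12), the last of which ended the immediate early call too (0.11). Normexp with its offset draws the differences of dim genes toward 0 by construction. Quantile normalization put Wnt targets apart (-0.15). Against unmatched random lists, ribosomal proteins gained a call (-0.12), while autophagy (0.14), epithelial (0.14), immediate early (0.15) and oxidative phosphorylation genes (0.069) lost it. List means ended the calls of NF-kB (0.24), epithelial (0.031), immediate early (0.11) and interferon genes (0.11), and put FOXO (0.22), apoptosis (0.19), Wnt (-0.15) and glycolysis genes (-0.15) apart.

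Genes with several probes left fewer members per list. The calls ended for MYC (-0.29, 4 genes), NF-kB (0.056, 5), interferon (0.19, 4), p53 (0.10, 10), autophagy (0.17, 8) and proteasome genes (-0.18, 6). The medians turned for immediate early (-0.18, 2 genes), epithelial (-0.050, 4) and oxidative phosphorylation genes (-0.00016, 7). FOXO (0.24, 8) and siRNA machinery genes (-0.32, 4) newly stood apart. Fewer genes widen the range of random lists, but where a median turned the cause was not tested, nor was it for the other alternatives on lists.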

Other observations

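The further gene lists, the single genes named here, the block correction and the tests on chaperone genes, growth state and added leukocyte signal were chosen only after results had been seen. Amino acid response genes outside the fixed stress list were lower in ZNF746 siRNA in 30 of 33 cases, with a median of -0.44 (percentile 0), and 1 of them is also in a fixed list. PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate, was at -1.07, the alanyl-tRNA synthetase AARS1 at -0.98, the transporters SLC7A1 and SLC7A5 at -0.96 and -0.93, and GPT2, an alanine transaminase, at -0.92. KLHL24 went the other way at 0.86. Nucleotide synthesis genes were lower in 19 of 20 cases (median -0.21, percentile 0.25), led by the purine enzymes PFAS (-0.69) and PAICS (-0.61). Ribosome assembly genes outside the fixed MYC list were lower in 25 of 31 cases (median -0.24, percentile 0.01).

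NRF2 targets were higher in 16 of 19 cases (median 0.21, percentile 99.96), with AKR1C3 at 1.06, the drug transporter ABCC3 at 0.78 and HMOX1, a heme oxygenase, at 0.74, while TXNRD1 was at -0.40. Mitochondrial ribosomal proteins (median -0.083, percentile 24.1), antigen presentation genes (-0.055, percentile 37.5) and cilium genes (0.048, percentile 71.0) did not stand apart. Among proteasome genes, PSMA3 (-1.17) and PSMA4 (-0.88) lay below the other 25, the next of which was PSMD4 at -0.39.

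The proliferation lists (G1/S, G2/M, MYC, DNA repair and histones) were lower together in ZNF746 siRNA. After loess on mean signal their medians were between -0.46 and -0.30 and the highest of the 5 percentiles was 0, and after the block correction it was again 0. The medians argue against an intensity trend as the whole source, where the percentile adds little because matching on signal had taken up most of such a trend, and the block percentile argues against spot position. The growth state of the cultures cannot be told apart from the siRNA, because there was 1 array per group. An effect of losing ZNF746, off-target effects of the siRNA and RNA quality stay open and were not tested.

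The stress and unfolded protein response list was lower in ZNF746 siRNA. The separate amino acid list, written before its own values were seen, had a percentile of 0, the outcome predicted for lower expression of the ATF4 amino acid programme. It was chosen after the fixed list was seen to be lower and holds genes of the same response. A low outcome was therefore likely in advance and does not single out ATF4. Of its 33 measured members 30 were lower, while ATF5 was at 0.30 and CBS at 0.010. The 11 chaperone and folding genes of the fixed list, 9 of them lower, had a median of -0.13 at percentile 17.4, which leaves a lower chaperone arm open because they were set apart after some had been seen to differ less. Spot position is argued against by a percentile of 0 for the fixed list after the block correction. Whether the medium, cell density or the siRNA lay behind the difference was not tested, so lower expression of these genes may reflect the culture rather than ZNF746.

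The leukocyte marker list was higher, and upward drift of dim probes stays open, because matching on signal holds the percentile after loess (99.25) near its first value and normexp, which shrinks dim differences, took the median from 0.35 to 0.075 (percentile 85.9). A separate list of abundant leukocyte transcripts, with its prediction set down before its values were seen, had 12 of 12 measured members higher (median 0.29, percentile 99.18), so leukocyte RNA in the ZNF746 siRNA sample may contribute and stays open. These 12 ranged from 0.009 for TYROBP to 0.70 for HCLS1. All 12 were also well above background in control siRNA, as measured genes must be, and 1 of them is in a fixed list. The brightest marker, CD79A, had an intensity of 2566 in control siRNA and 3563 in ZNF746 siRNA. After that outcome 2 further checks were tried in turn. In the first, 9 of 14 transcripts chosen as blood-restricted were above background in ZNF746 siRNA, against 8 in control siRNA. The added transcript was SRGN, with an intensity of 7.73 in control siRNA and 8.68 in ZNF746 siRNA, so the count decides little. In the second, the 6 abundant members without signal in control siRNA gained a median intensity of 0.081, against 4.41 for the 11 markers. CD74, S100A8, S100A9, LAPTM5 and CD53 were among those 6 and not well above background on either array. Nor were the markers MS4A1 (intensity 3.04 in control siRNA, 1.95 in ZNF746 siRNA) and GNLY (1.83 and 3.72). Values this near the floor gave little sign of added leukocyte RNA but cannot exclude a small share of it.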
